A study of Mus musculus with 2 samples.

How the data were processed

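Liver RNA of male mice on a high-fat diet was measured in 2 libraries, 1 labelled wild type and 1 labelled Lrg1 knockout. Per the labels, libraries were made from about 500 ng of total RNA with poly(A) selection and a stranded kit, and sequenced as single-end reads of 50 bases. The labels do not say whether a library came from 1 mouse or a pool, or at what hour or after what fast tissue was taken. Per the submitters' processing notes, the tools bcl2fastq, TopHat2 and HTSeq and the genome build mm9 were used; their versions, the strand setting of the counting and the gene annotation are not given in the sources used here. The authors deposited raw read counts per gene symbol, as whole numbers without normalization, and these counts were used as deposited.

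Each file held 22609 gene symbols and lines that name no gene. The latter were left out of library sizes. Reads outside genes made up 14.01% of uniquely aligned reads in the wild-type library and 14.44% in the library labelled Lrg1 knockout, and reads in more than 1 gene 0.231% and 0.234%. Lines for alignments that were not unique made up 50.3% and 58.0% of all counted lines. Since only unique alignments were counted to genes, members of near-identical families such as Mup, Cyp2, Serpina1 and ribosomal protein genes with pseudogenes are uncertain. Of the symbols, 20043 were current RefSeq symbols; older symbols were matched through synonyms. GENCODE M21 on GRCm38 was used only for gene structure, neighbourhood and transcript sequences, and no coordinates are given because the builds differ.

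Counts were scaled with the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.972 and 1.03. Log2 ratios of the library labelled knockout to wild type were taken after adding a prior count of 0.5. A gene counted as measured with at least 50 reads summed over both libraries, which gave 11411 genes holding 99.9% of reads. The ratio has an exact Clopper-Pearson interval at 95%, given the sum of both counts, and single counts have exact Poisson intervals. Both cover counting error only. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error. With 1 library per group no test between genotypes was possible and no p-value is given.

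Gene lists, 9 primary and 35 secondary, were each summarised by the median log2 ratio of their measured members. The percentile of that median was taken among 10000 random lists of the same size matched in 20 bins of mean expression, and a list stood apart below 2.5 or above 97.5. A list needed at least 3 measured members, which left 40 lists; T and NK cell, pancreatic acinar, skeletal muscle and mitochondrially encoded lists were not compared. Named genes were Lrg1, 22 metabolic genes, the 12 highest and 12 lowest log2 ratios among named genes with at least 300 reads, and in each list the 4 measured members farthest from 0. The lists, this rule, the comparisons and the alternatives were fixed before the data were examined. Genes named or drawn outside the rule (Arntl, Npas2, Cry1, Clock, Nfil3, Nr1d1, Per1, Per2, Elovl3, Cyp17a1, Slc2a2, Stard4, Ticam1 and Zfp119a) were chosen after their values were seen. Of others, Ddx3y belongs to a sex check fixed beforehand, and Cish and Bcl6 were named for a test before their values were seen. Some genes that the rule takes are not reported here.

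The steps were tested on a simulated pair of libraries with 11392 measured genes, in which 200 genes differed by known folds. Both simulated libraries were drawn by Poisson counting from the summed composition of the real libraries, at the depth of each. The pair holds no spread between mice or preparations, so the rates below describe counting error only and not the error of the real comparison. The 200 genes were drawn from those with at least 100 reads summed over both libraries. Recovery of genes with 50 to 100 reads was therefore not tested. Of 50 genes set 2.5-fold higher, 100% passed the 2-fold threshold, and of 50 set to 0.4 of wild type 96.0% did. Genes set to 1.5 or 0.667 passed in 0% and 2.0% of cases, and 3 of 11192 unchanged genes passed. Intervals covered the true fold for 93.0% of the 200 genes, and a list of 25 genes shifted by 0.3 on the log2 scale reached percentile 100.

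The alternatives were scaling by total count, by DESeq2 1.42.0 size factors and by total count without the 20 most abundant genes, thinning of the deeper library, a prior count of 2, minimum sums of 1, 10 and 200 reads, thresholds of 1.5-fold and 3-fold, list means, lists without their most different member, and 50 bins. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.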

Results

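RNA from the livers of male C57BL/6 mice was sequenced to ask how loss of Lrg1, a secreted leucine-rich glycoprotein made in liver and fat, relates to liver gene expression under a high-fat diet. Mice received a diet with 45% of calories from fat from 8 weeks of age for 16 weeks. There were 2 libraries, 1 labelled wild type and 1 labelled Lrg1 knockout. The wild-type library held 23311906 reads in genes and the library labelled Lrg1 knockout 18738397, over 15159 and 14966 genes with at least 1 read. In CPM, the read count scaled to TMM-adjusted library size, 1 read corresponded to 0.0441 and 0.0519, and a gene without reads could lie at up to 0.132 and 0.156 CPM (3 counts). Intervals below are 95% intervals for counting error only. With 1 library per group there is no replicate check, so every difference compares these libraries and not the genotypes.

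Lrg1 itself was abundant in both libraries, although 1 of them is labelled Lrg1 knockout. It had 26958 reads in the wild-type library, 1190 CPM (1176 to 1204), and 17572 reads in the library labelled Lrg1 knockout, 911.2 CPM (897.8 to 924.8; exact Poisson intervals). The ratio of the library labelled knockout to wild type was 0.766 (exact interval 0.751 to 0.780), a log2 ratio of -0.39. That ratio lay at the 11.2 percentile of the 8459 genes with at least 300 reads, and 14 of 29 measured acute phase genes, the class of liver secretory genes to which Lrg1 belongs, had a lower ratio. Lrg1 lies on chromosome 17 with 1 annotated protein-coding transcript of 2 exons (ENSMUSG00000037095). Among 39 measured genes within 1 Mb of it, 0 were 2-fold higher and 0 were 2-fold lower, with log2 ratios from -0.89 for Ticam1 to 0.54 for Zfp119a. Because the counts do not show where in the gene the reads lie, and the deleted part is not given in the sources used here, the label could not be checked further. Every direction below is therefore drawn from a library labelled knockout that held Lrg1 reads.

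Most lipid synthesis, protein folding and circadian clock genes were lower in the library labelled Lrg1 knockout, while male-biased liver genes and markers of sinusoidal endothelium were higher. Of 11411 measured genes, 194 were at least 2-fold higher and 285 at least 2-fold lower in it, together 4.2% of measured genes. Ctse, which encodes the protease cathepsin E, had the lowest log2 ratio among named genes with at least 300 reads, with 3061 reads in wild type against 35 (73.5-fold higher in wild type, 53.4 to 107). Rgs16, a regulator of G protein signalling, had 3338 against 84 reads. At the other end stood Hsd3b5, a steroid dehydrogenase of male liver, with 158 reads in wild type and 1750 in the library labelled knockout (13.0-fold higher, 11.1 to 15.4). Gadd45g, a stress and growth arrest gene, followed at a log2 ratio of 3.53, then Socs2 at 3.23 and Hhex, a homeobox transcription factor, at 2.77. Across measured genes the libraries correlated with Pearson r 0.979 and Spearman rho 0.978. Genes are not independent replicates, and a simulated pair differing by counting alone gave r 0.998 and 3 genes 2-fold apart.

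**Figure D1:**
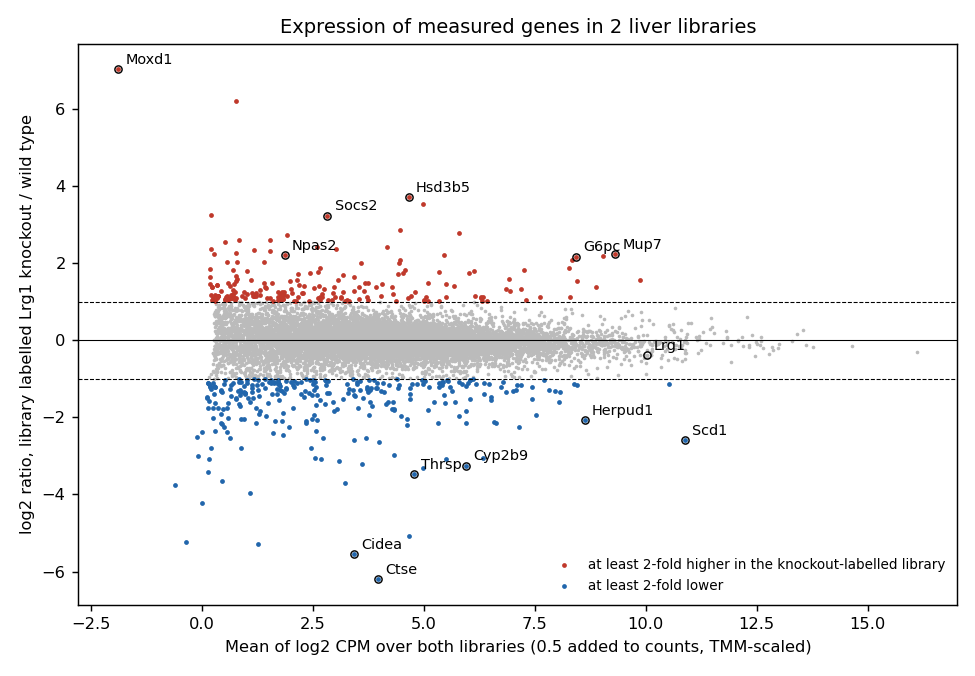
Log2 ratio of the library labelled Lrg1 knockout to the wild-type library (vertical axis) against mean log2 CPM (horizontal axis) for 11411 measured genes, with 194 genes at least 2-fold higher in red and 285 at least 2-fold lower in blue. Lrg1 lies between the dashed 2-fold lines at -0.39, while Scd1 lies at -2.60; Moxd1, with 0 wild-type reads, is drawn at a ratio set by the prior count.

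Genes of fatty acid, cholesterol and triglyceride synthesis had lower expression in the library labelled Lrg1 knockout. Scd1, the desaturase that makes monounsaturated fatty acids, went from 4617 CPM in wild type to 763 CPM, a log2 ratio of -2.60. In the de novo lipogenesis list 20 of 22 measured genes were lower and 6 were at least 2-fold lower, among them Thrsp, a lipogenic regulator (-3.47), and Aacs, which activates acetoacetate (-1.97). Fasn, the fatty acid synthase, was at -1.53 and Srebf1, the transcription factor that drives these genes, at -0.70. Acly, which makes cytosolic acetyl-CoA, was at -0.34, and the interval of Acaca, acetyl-CoA carboxylase (-0.12), included no difference. The median of the list, -0.47, lay at percentile 0 among 10000 random lists matched on expression.

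Cholesterol synthesis and uptake genes had a median of -0.56 (percentile 0), with 20 of 22 below 0 in the library labelled knockout. Mvd, an enzyme of the mevalonate pathway, was at -1.88 and Stard4, a sterol transfer protein, at -0.79. Triglyceride synthesis and lipid droplet genes had a median of -0.34 (percentile 0), with 22 of 29 lower. Cidea, a droplet fusion protein, had 1667 reads in wild type against 30 (46.6-fold higher in wild type, 33.0 to 70.3). Lpin1, a phosphatidate phosphatase, was at -3.05, Mogat1, a monoacylglycerol acyltransferase, at -1.80, Cidec at -1.40 and the fatty acid transporter Cd36 at -1.33. Pparg, a lipogenic nuclear receptor, was at -0.57, and among droplet coat genes Plin4 was at -0.59, Plin5 at -0.25 and Plin2 at 0.08.

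Fatty acid oxidation and lipoprotein genes did not stand apart from other genes. The oxidation and PPAR alpha list had a median of -0.07 (percentile 58.5), 14 genes higher and 18 lower, and this median turned to 0.02 when libraries were scaled by total count. Pdk4, which slows glucose oxidation, was at 1.14 and Ehhadh, a peroxisomal enzyme, at 0.84, while Cpt1a was at -0.14, Ppara at -0.22 and Fgf21, a hormone secreted by liver, at -0.10 with an interval that included no difference. Acot1, at 0.72, belongs to a family of near-identical genes and is uncertain. Lipoprotein genes had a median of -0.10 (percentile 32.5), with the sorting receptor Sort1 at 1.48 and the phospholipid transfer protein Pltp at -1.08.

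Glucose output genes went both ways in the library labelled Lrg1 knockout. G6pc, the last enzyme of glucose release, was 4.47-fold higher (4.31 to 4.64), Ppp1r3c, a glycogen-targeting phosphatase subunit, was at 1.33, and Pck1, the gluconeogenic carboxykinase, was at 0.58. In the same list Slc37a4, which carries glucose 6-phosphate into the endoplasmic reticulum, was at -1.15 and Ppp1r3b, a glycogen-targeting subunit of liver, at -1.03. The median was -0.25 (percentile 0.37), with 7 genes higher and 13 lower, but the mean was -0.03 at percentile 67.2, inside the range of random lists, as was the median from 200 reads (-0.18, percentile 3.76). Insulin signalling components had a median of 0.02 (percentile 74.5) and a mean of 0.34 (percentile 100). Socs2, a feedback inhibitor of cytokine receptors, was at 3.23, the kinase Sik1 at 2.41, the binding protein Igfbp1 at 1.80 and the insulin receptor substrate Irs2 at 1.37. Irs1 was at 0.73, and Insr, the insulin receptor, was at -0.01 with an interval that included no difference.

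Acute phase genes had a median of -0.37 (percentile 0), with 23 of 29 lower in the library labelled Lrg1 knockout. Orm3 was at -2.55, Lcn2, an iron-siderophore binding protein, at -2.14 and Orm2 at -1.03, whereas Hamp, the iron hormone hepcidin, was at 1.81. Orm and Saa genes are close copies, so their individual values are uncertain. Inflammatory cytokine and NF-kB target genes had a median of 0.12 (percentile 88.0) and a mean of -0.02, with Cxcl1, a neutrophil chemokine, at -3.14, Tnfaip3, an NF-kB inhibitor, at -1.67, Il1b at 1.40 and Il1a at 1.24. Interferon response genes had a median of -0.20 (percentile 0.21), 24 of 30 lower, but 0 were 2-fold lower; Oas1a was at -0.88 and Isg15 at -0.81.

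Protein folding genes had lower expression in the library labelled Lrg1 knockout. The endoplasmic reticulum stress list had a median of -0.76 (percentile 0), with 18 of 20 lower and 8 at least 2-fold lower. Creld2 was at -2.12, Herpud1, which serves degradation of misfolded proteins, at -2.08 and Sdf2l1 at -1.80. Asns, the asparagine synthetase, was higher at 2.55 on 13 and 67 reads. Heat shock genes had a median of -0.43 (percentile 0.01), with 12 of 12 lower, among them Hspa1b at -1.30 and Hsph1 at -0.93.

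Circadian clock genes were among the genes most different between the libraries. The list had a median of -1.05 (percentile 0), with 15 of 20 lower and 10 at least 2-fold lower in the library labelled Lrg1 knockout. Ciart, listed under its older symbol Gm129, had 342 against 7 reads (-5.29), Usp2 was at -3.71, the clock output factor Dbp at -3.31 and the repressor Per3 at -3.08. The 5 higher members were Npas2 (2.21), Arntl (1.49), Nfil3 (0.94), Cry1 (0.79) and Clock (0.33). Immediate early genes had a median of -0.17 (percentile 4.90), inside the range of random lists, but stood apart from 200 reads (-0.38, percentile 0.02) and by their mean (-0.30, percentile 2.43), with Egr1 at -3.09, Junb at -1.32, Zfp36 at -1.08 and Nr4a1 at 2.42.

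Sex-biased liver genes differed in opposite directions. All 25 measured male-biased genes were higher in the library labelled Lrg1 knockout, 13 of them at least 2-fold, with a median of 1.12 (percentile 100). Besides Hsd3b5, Ugt2b38 was at 2.61 and Mup1 at 2.35. Moxd1 had 0 reads in wild type and 59 in the other library, at least 23.1-fold higher against a floor of 3 counts in the wild-type library; the exact interval, which also covers counting error in the 59 reads, starts at 18.2-fold. With Moxd1 at the bound from the floor the list mean was 1.30 in place of 1.40, while the median, 1.12, cannot respond to it. Of 13 measured female-biased genes, 10 were lower and 7 at least 2-fold lower, with a median of -2.24 (percentile 0). That median was -1.52 among members with at least 200 reads, and also without the most different member. Cyp2c69 was at -3.95, Cyp2a4 at -3.64, Cyp2b13 at -3.43 and Cyp2b9 at -3.26. The Mup, Cyp2 and Ugt2b families hold near-identical copies, so single members are uncertain. The Y-linked genes summed to 3782 and 3166 reads, a ratio of 0.983 (0.938 to 1.031), and Xist, which is expressed from the inactive X chromosome, had 69 reads in wild type and 12 in the other library. Nnt, which C57BL/6J mice carry in a deleted form, was at -0.08.

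**Figure D2:**
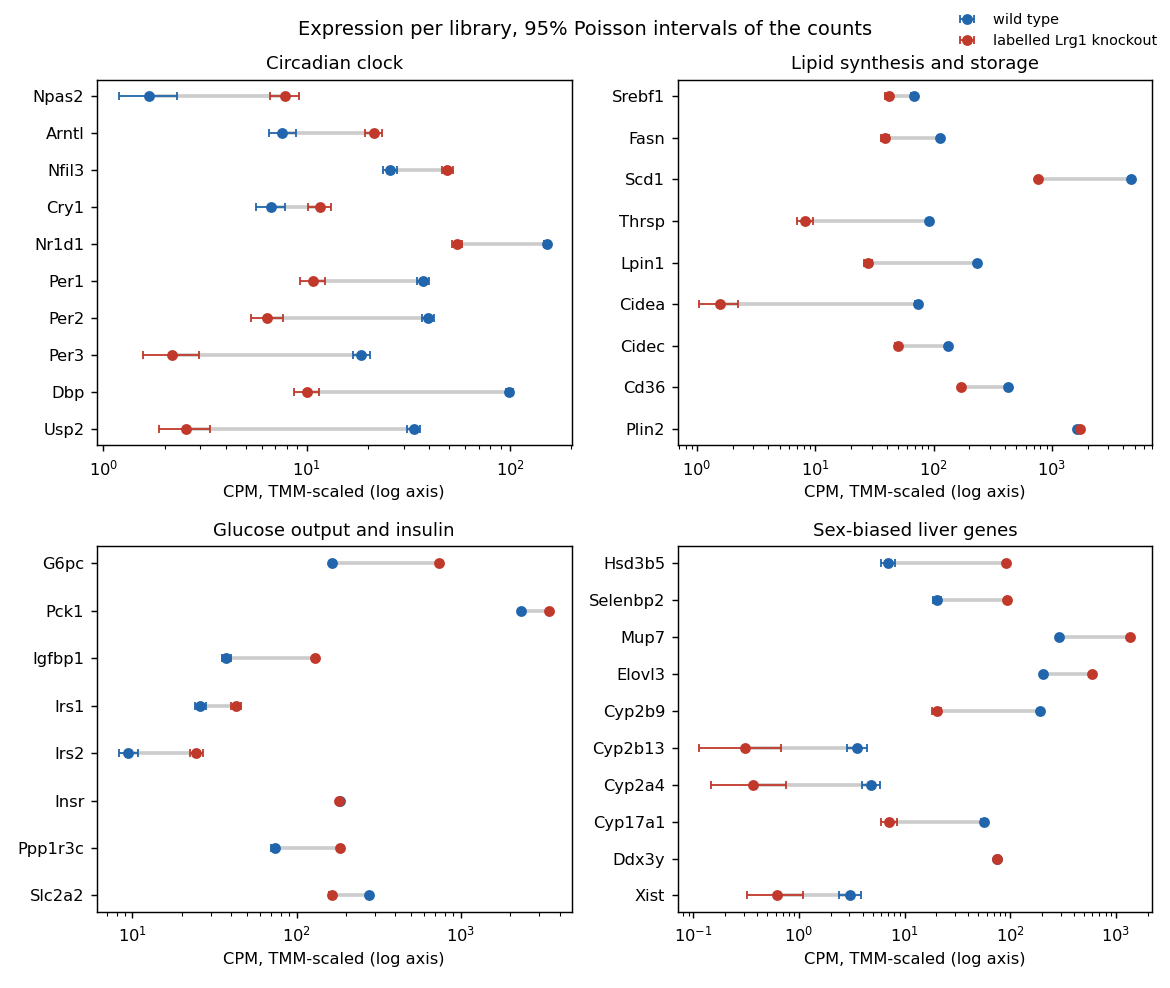
Expression in CPM (horizontal log axis) of genes from clock, lipid, glucose and sex-biased groups in the wild-type library (blue) and the library labelled Lrg1 knockout (red), 1 library each; bars are 95% Poisson intervals of the counts. Scd1 lies at 4617 CPM in wild type and 763 CPM in the other library, whereas Ddx3y, a Y-linked gene, lies at 74.9 and 75.1 CPM.

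Of 40 gene lists compared, 4 had a median above and 14 a median below the central range of their random lists, where 2 would be expected if lists were random draws. The percentiles describe these libraries, and genes within a list are not independent.

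**Figure D3:**
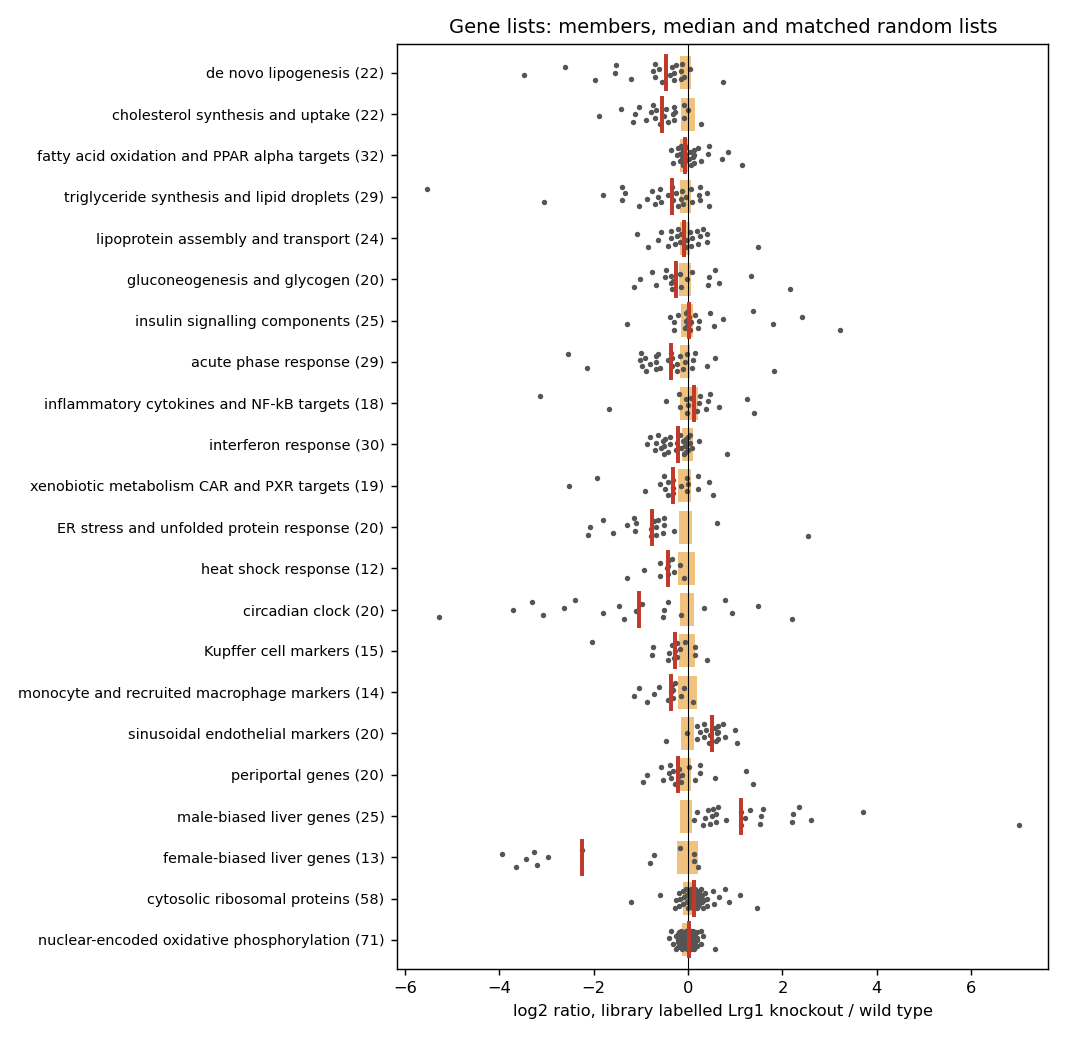
Log2 ratio of the library labelled Lrg1 knockout to the wild-type library (horizontal axis) for measured members (grey points; number in parentheses) of 9 primary lists and of the secondary lists whose median lay outside the range of random lists. Red bars are medians and orange boxes the central 95% of the medians of 10000 random lists; the male-biased median lies at 1.12 and the female-biased median at -2.24, and the point farthest right is Moxd1, placed by the prior count.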

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

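No test of an explanation was run in this part. Lines for alignments to more than 1 place, which lie outside the counts per gene, made up 58.0% of all counted lines in the library labelled Lrg1 knockout and 50.3% in the wild-type library. They drew attention as a large signal in data that the comparisons do not use, above the limit that a count of 0 allows. They numbered 30368128 and 27554856 lines, or 1.62 and 1.18 per read counted in genes, and a read with several alignments can enter more than once. Which genes or repeats they came from is not analysed here.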

How the results depend on the processing

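The alternatives were chosen in advance, and none was added. The log2 ratio of Lrg1 stayed below 0, at -0.30 under total-count scaling and -0.33 under total count without the 20 most abundant genes. Scaling by total count moved named genes by about 0.08 (log2), too little to reverse the direction of a 2-fold difference. That size holds for scaling only. A prior count of 2 or thinning can move genes with few reads further, above all Moxd1, which had 0 wild-type reads. Under the alternative scalings, thinning and prior, 0 named genes that were 2-fold apart changed direction. Of the 18 lists that stood apart, 15 did so under all 11 alternatives for lists. The number of genes 2-fold higher and lower in the library labelled knockout follows from the filter and threshold by construction: 1243 and 1449 without a filter, 458 and 525 from 10 reads, 100 and 166 from 200 reads, 667 and 789 at 1.5-fold, and 51 and 105 at 3-fold. From 10 reads the adipocyte list stood apart at -0.60, but its median was 0.05 without a filter and without its most different member, so its direction is not settled. From 200 reads gluconeogenesis and glycogen no longer stood apart (-0.18), while immediate early genes (-0.38) and the few cell cycle genes left (-0.54) did. With means, gluconeogenesis (-0.03), periportal genes (-0.075) and oxidative phosphorylation (0.002) no longer stood apart, while insulin signalling (0.34), immediate early (-0.30) and adipocyte genes (-0.56) did. The other small lists also moved with the filter: without one, and from 10 reads, the erythroid median was -0.06 and -0.07, the cholangiocyte median 0.13 and 0.01, and the B cell median 0.64 and 0.42. Without its most different member the cholangiocyte median was 0.01. The B cell, neutrophil and erythroid lists had too few measured genes for a value from 200 reads or without a member, as had B cell and neutrophil lists after thinning. From 200 reads the inflammatory median was -0.03. Without its most different member the TGF beta and BMP list stood apart at 0.16. For the lists, the cause was not tested. Scaling by total count moved the share of higher genes among those 2-fold apart from 40.5% to 48.5%, with 236 higher and 251 lower. Median and mean differed in sign for fatty acid oxidation, inflammatory, fibrosis and pericentral genes. Depth limits genes under 50 reads, where 1 read is worth 0.0441 or 0.0519 CPM.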

Other observations

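The tests of library origin, kept transcript part, hour of collection, fasting and female RNA were chosen only after the result was seen. That of shared reads was chosen before. The test of growth hormone signalling was prompted by the value of Socs2, but chosen before those of Cish and Bcl6 were seen.

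Sinusoidal endothelial markers were higher in the library labelled Lrg1 knockout, with 18 of 20 above 0 and a median log2 ratio of 0.52 (percentile 100). Dnase1l3, a secreted nuclease, was at 1.04. Kdr, a VEGF receptor, had 517 reads in wild type and 882 in the other library, and Fcgr2b was at 0.79 and Bmp2 at 0.74. Most macrophage markers went the other way. Kupffer cell markers had a median of -0.27 (percentile 0.39), with 12 of 15 lower and 3 higher. Only 1 of them was at least 2-fold lower, the scavenger receptor Marco at -2.04, and Timd4 was at -0.77. Recruited macrophage markers had a median of -0.35 (percentile 0.11), with 13 of 14 lower, among them Gpnmb at -1.14 and Lyz2, a lysozyme, at -1.05. Fibrosis and stellate cell markers (0.04, percentile 70.0; Col1a1 -1.07), MHC class II genes (0.15, percentile 89.4), TGF beta and BMP targets (0.11, percentile 92.9; Id3 1.12) and cell cycle genes (-0.12, percentile 19.8) did not stand apart. Cell cycle members with at least 200 reads did (-0.54, percentile 0.74). They were few and went both ways, with Mcm4 at 0.81, Cdkn1a at -0.89 and Ccnd1 at -0.97. Without its most different member the TGF beta and BMP list also did (0.16, percentile 97.9). The short lists for B cells (0.10), neutrophils (0.16), cholangiocytes (-0.06), erythroid cells (0.17) and adipocytes (-0.25, 5 measured genes, among them Pck1 of the gluconeogenesis list, with Cfd at -2.54) did not stand apart either. These rest on 3 to 5 measured genes, and the erythroid, cholangiocyte and adipocyte medians changed sign with the filter on low counts.

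Hepatocyte identity genes had a median of -0.03 (percentile 83.3) with 0 of 25 genes 2-fold apart, a direction that turned to 0.05 under total-count scaling and 0.03 without the 20 most abundant genes. Xenobiotic genes had a median of -0.32 (percentile 0.09), with Cyp2b10 at -2.53, Cyp2a5 at -1.94 and the reductase Por at -0.92. Bile acid genes (-0.06, percentile 56.2) did not stand apart, with Cyp7b1 at 1.12, the nuclear receptor Nr0b2 at -1.61 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.85. NRF2 targets (-0.10, percentile 20.9; Gstm3 -3.05, Nqo1 -1.38), urea cycle genes (-0.12, percentile 21.1), pericentral genes (-0.13, percentile 13.4; the vasopressin receptor Avpr1a had 245 and 836 reads), hepatokines (-0.11, percentile 17.7; Gdf15 -2.21, Tsku -2.16), proteasome genes (-0.01, percentile 80.2) and the sex and substrain check genes (-0.09, percentile 27.7) did not either. Under total-count scaling the medians of bile acid genes (0.02), cholangiocyte markers (0.03) and proteasome genes (0.08) turned above 0. Periportal genes had a median of -0.20 (percentile 1.78) but a mean of -0.075 inside the range of random lists, with 2 genes 2-fold higher, among them Cdh1 at 1.38, and 0 lower. Ribosomal protein genes (0.14, percentile 99.8) and oxidative phosphorylation genes (0.03, percentile 98.9) lay slightly above their random lists, the former uncertain because of pseudogenes and the latter inside the random range by its mean (0.002).

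Lrg1 reads were present in the library labelled Lrg1 knockout at a ratio of 0.766 to wild type. Reads shared exactly with the transcript of another gene are argued against. Of 1359 windows of 50 bases in the Lrg1 transcript, 0.0% occurred in transcripts of other genes. Alignments that were not unique were also left out of the counts. Near matches and sequence outside annotated transcripts were not searched. A library that did not come from knockout liver stays open: the ratio lay at the 11.2 percentile of well-counted genes, where loss of the transcript would place it near the bottom. Transcript from a kept part of the gene cannot be told apart from this, because counts per gene do not show where reads lie. The ratio of 0.766 was above the share of exon bases outside the coding sequence, 26.9%. That share decides nothing here, since the kept part and its expression are not known. Both remain candidate explanations, and how the allele was made is not given in the sources used here.

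Clock and lipogenic genes differed between the libraries, as did G6pc, while the gluconeogenesis list as a whole went both ways. A different hour of collection is a candidate explanation. In the library labelled Lrg1 knockout, 5 of 5 genes that peak around the end of the night were higher. In it 11 of 11 day and evening genes were lower, with medians 3.33 apart on the log2 scale. Both sets were picked from the clock list after its values were seen, and the 5 are its only higher members. The counts therefore restate the clock pattern and are no separate evidence for this explanation. Many lipogenic genes and G6pc also follow feeding and time of day. A longer fast before collection cannot be told apart. The fatty acid oxidation list lay at percentile 58.5 by its median and 96.8 by its mean, with members going both ways. This result was first read as arguing against a longer fast, and the reading was changed to undecided after the values were seen. An effect of genotype was not tested and stays open, as the design has 1 library per genotype.

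Sex-biased liver genes differed although both libraries are labelled male. Female RNA in the wild-type library is argued against for the male-biased genes, since Y-linked genes had a ratio of 0.983 (0.938 to 1.031) where the median male-biased gene had 2.18. For the female-biased genes a small share of female RNA cannot be told apart, because the Y-linked interval allows up to 3.0% and Xist was higher in wild type. Growth hormone signalling that differed at collection is a candidate explanation. Its target Cish was at 1.74 and Bcl6, which growth hormone represses, at -1.12. These values do not show whether such a difference accounts for the sex-biased genes. Socs2 had prompted the test and does not count toward it. An effect of genotype was not tested and stays open.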
